A study of Mus musculus with 2 samples.

How the data were processed

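Chromatin accessibility was measured by DNase-seq in liver of adult C57BL/6J mice after 54 hours of constant darkness, at circadian time 42. The labels describe 2 libraries as technical replicates 1 and 2 of biological replicate 1, which form 1 group here. The labels give the genome build mm10 and no tool, version or setting of the read processing, which are not given in the sources used here.

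The deposited files came from 2 processing runs of the same sample, called run A and run B here for want of other names. Per the file headers and lists that accompany each library, every file used derives from an alignment listed for both libraries, so the libraries were pooled before peaks were called and no deposited value belongs to a single library. The peak heights deposited by the authors for run A are a signal scaled by depth. Each height under 200 steps was a whole multiple of 1 step within a tolerance of 0.02, the step being 0.00376, which corresponds to 266 M cuts if 1 step is 1 cut. The run B peak heights were deposited as a signal in whole numbers that is not scaled. For shared peaks, the median of the run B height over the run A height in steps was 1.03. For the hotspots the authors deposited −log10 q values in the ninth column, from 1.30 to a cap of 100, and a score of about 10 times that value. The deposited site-wise files hold q-values of the local cut rate up to 0.05 in each run. In run B 128 intervals (30290 bases) had a q-value with an exponent so low that it reads as 0, and they were kept as the lowest values. The footprints carry the same deposited value of 0.01 in each row, which was taken to be the threshold and could not rank them.

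The design fixed before the data were examined allowed for files per library. Since none was, the planned comparison of the libraries became one of the 2 processing runs, and the planned results without 1 library could not be made. The larger run A list was chosen as the main peak list before gene results were seen, and the smaller run A list and the run B list served as alternatives. All run A peaks reached an FDR of 0.05 and 74.0% of the larger list reached 0.001, as did 100% of the smaller list.

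Coordinates were checked against the GRCm38 assembly, whose coordinates are those of mm10: no region ran past a chromosome end, and 5 peaks of the larger list touched an assembly gap. Genes and TSS came from GENCODE release M21. Overlaps needed at least 1 base and were counted beside 20 seeded random placements with bedtools 2.31.1. A peak midpoint within 1 kb of a TSS was called promoter, otherwise exon, intron or between genes. A gene's promoter height was that of the tallest peak reaching within 1 kb of any of its TSS, or 0.

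There were 29 gene lists and 34 consensus motifs, fixed before the data were examined. Of the listed genes, Amy2b was not used here because the protein-coding set did not hold it, and C5 and Hc are 1 gene. For each list the median promoter height, and the median number of peaks in the gene or within 10 kb, were placed among 10000 random lists of the same size drawn from 21911 protein-coding genes, matched in 10 bins of promoter CpG content or of gene length. The percentile describes this sample and is not a p-value. A list was called high at the 97.5th percentile and low at the 2.5th. The genes named are all clock genes, the 3 genes with the tallest promoter peak and 1 with the lowest or none in each other list, up to 5 genes with a peak in each list of a tissue not sampled, and the nearest genes of the 10 tallest peaks. Some genes that this rule would name are not reported here.

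Motifs were matched exactly on both strands. In footprints widened by 5 bases and cut to the peaks (9.73 Mb), sites per kb were divided by those in the other 45.2 Mb of the peaks, with an exact interval for a ratio of counts. In distal peaks, windows of 100 bases on each side of the centre were compared with equal windows past the end of the peak, where no other peak lay, which left 177889 of 200821 peaks. Each motif was set beside up to 20 column shuffles, and a motif with fewer than 10 usable shuffles was not placed. Shares have 95% Wilson intervals. DNase cuts without molecular identifiers are not independent molecules, so intervals cover counting error only.

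The alternatives were other promoter and gene windows, unmatched random lists, the peaks at or above the median height, the other peak lists, other footprint flanks, footprints outside promoters and other FDR levels. Added after seeing the data were the promoter share in the other peak lists, the gene lists without 77 peaks of a stretch on chromosome 1 and of isolated tall sites, and the footprints at or above the median length. Second matches of peak sequences were searched with BLAST 2.17.0 in the chromosomes at 90% identity over at least 36 bases, and matches of at least 30 bases in mitochondrial DNA. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and plots matplotlib 3.10.9.

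The methods were tested on simulated data with known answers. Among 200 simulated unchanged lists over the 21911 genes, 8 reached the 97.5th percentile, and of 200 lists raised 3 times 180 did. The motif scan found 398 of 398 planted sites, the ratio interval held the true ratio in 1917 of 2000 simulations, and the overlap counts equalled those of bedtools (943 of 943).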

Results

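DNase-seq, which reads open chromatin from the sites where the enzyme DNase I cuts nuclear DNA, was carried out on liver of adult C57BL/6J mice aged 8 to 10 weeks. The animals had spent 54 hours in constant darkness and were taken at circadian time 42. The sex of the animals was not collected, per the labels. The series held 2 libraries, technical replicates 1 and 2 of 1 biological sample, and no second condition, so the question it can answer is which genes, regions and sequence motifs lay in open chromatin in this liver at this time. Peaks, hotspots, footprints and site-wise false discovery rates (FDR) were deposited for both libraries pooled, in 2 processing runs called run A and run B here. No value had a replicate error, and the intervals given cover counting error only.

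Open chromatin was concentrated in a small part of the genome. The larger run A list, used for the results unless another is named, held 250137 peaks that covered 54.9 Mb, or 2.01% of the genome, with a median width of 200 bases. The peaks are narrow calls: run A marked 107 Mb at an FDR of 0.05, of which 50.6% lay in these peaks. The run B hotspots covered 4.08% of the genome. Peak heights, in units scaled by depth, ran up to 61.3 with a median of 0.454, and the steps between heights corresponded to a depth of 266 M cuts if 1 step stands for 1 cut. The smaller run A list held 182738 peaks, run B 260783 peaks and 210278 hotspots, and run A 528124 footprints (short protected stretches inside open chromatin, median width 9 bases). Footprints lay in the peaks in 89.0% of cases against 2.36% after random placement, and 69.8% of the peaks held at least 1 footprint. Both were called from the same libraries, so this overlap is a description and no independent test. Chromosome 11 had 134 peaks per Mb, chromosome X 39.7 and chromosome Y 1.44. On chromosome Y the promoters of Uty, Ddx3y, Eif2s3y and Kdm5d, which were looked up after the first results were seen, each held a peak, with heights of 3.74, 2.204, 2.19 and 1.78.

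Promoters were open far more often than chance. Of all peaks, 19.7% (95% Wilson interval 19.6 to 19.9) lay within 1 kb of a transcription start site (TSS), against 6.29% of randomly placed peaks. Introns held 43.8%, exons 4.86% and the space between genes 31.6%, where random placement gave 40.1%, 3.37% and 50.2%. The promoter share grew with height, from 9.68% in the lowest 20% of peaks by height to 34.4% in the highest 20%. Among 21911 protein-coding genes, 15323 (69.9%, interval 69.3 to 70.5) had a peak within 1 kb of a TSS, and the median height over all of them, with 0 for a gene without a peak, was 1.70. The promoter share depended on the window, being 13.1% within 500 bases and 31.4% within 2500 bases.

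The tallest peaks fell into a cluster and a scatter of isolated sites. The tallest, with a height of 61.3, lay in an intron of Trpm8, a cold-sensing ion channel gene, on chromosome 1 from 88288181 to 88288380 (GRCm38, as for the positions that follow). The other peaks among the 10 tallest on chromosome 1 near it were at the Hjurp and Trpm8 TSS (88277501 to 88277780, 31.8), in an intron of Trpm8 (88279161 to 88279440, 27.95) and in an intron of Ugt1a1 (88213721 to 88213940, 24.3). The second tallest peak (57.9) lay in Kpna1 on chromosome 16 from 35981641 to 35981800, the third (53.1) in an exon of Lars2 on chromosome 9 from 123461981 to 123462060, and the fourth (47.6) on chromosome 1 from 195241541 to 195241820, nearest to Cr2, with a height in run B of 0.614 times that in run A after scaling by the typical ratio of the runs. Peaks between genes near Pak3 on chromosome X (143483001 to 143483140, 38.1), in an intron of Jarid2 on chromosome 13 (44869561 to 44869700, 35.9) and nearest to Ddx18 on chromosome 1 (122357141 to 122357300, 24.9) completed the 10. Each of these 6 isolated peaks had from 1 to 12 near-identical matches elsewhere in the genome. The heights near Ugt1a1, Hjurp and Trpm8 stood in a stretch whose lower heights were high as well, as set out in the closing section. The order of the tallest peaks differed in run B, where the peak nearest to Ifna13 was highest (17437) and the Trpm8 peak reached 15989.

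**Figure D1:**
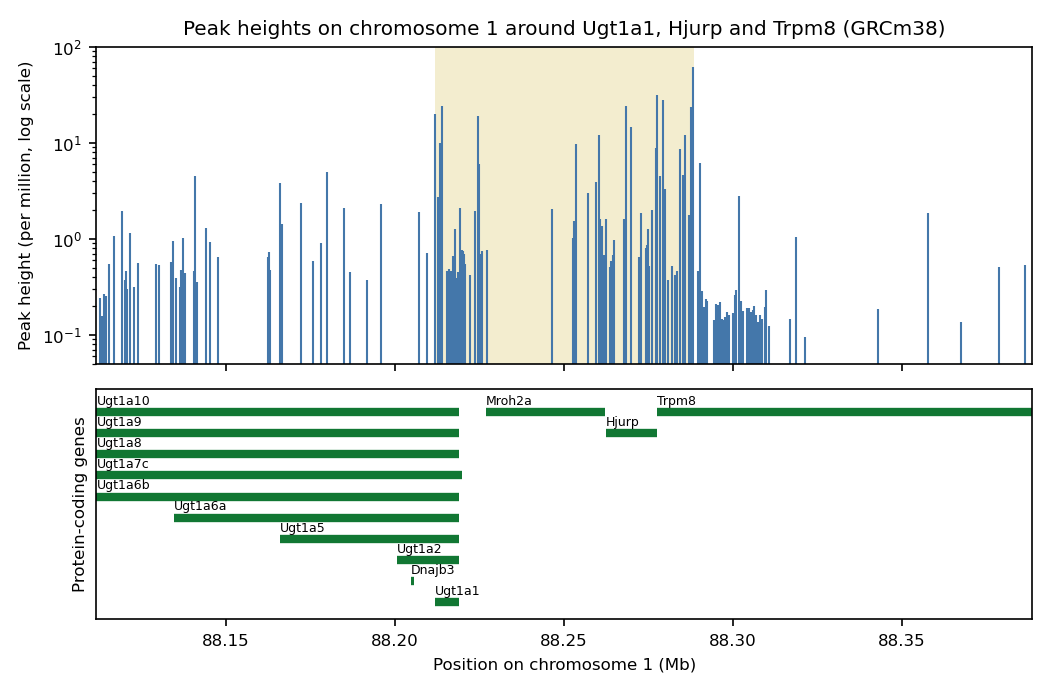
Peak heights in the larger run A list (upper panel, depth-scaled units, log scale) against position on chromosome 1 in Mb, with protein-coding genes as bars below; the shaded stretch runs from 88211801 to 88288380. Its 63 peaks have heights of at least 0.376 and a median of 1.52, while the 87 peaks within 100 kb on each side have a median of 0.312.

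The promoters of the circadian clock were open throughout. The 22 clock genes all had a peak, and their median height of 6.65 compared with 3.61 for random lists of the same size matched on promoter CpG content and stood at the 99.99th percentile of 10000 such lists. The nuclear receptor genes Nr1d2 and Nr1d1, which encode the REV-ERB repressors, had the tallest promoter peaks of the list, at 10.2 (chromosome 14, 18239081 to 18239380) and 9.32 (chromosome 11, 98775281 to 98775560). Per1, a gene of the negative limb, followed at 8.81 (chromosome 11, 69094781 to 69095260), and Arntl, which encodes the activator BMAL1, at 8.20 (chromosome 7, 113207081 to 113207480). Dbp reached 8.01, Cry2 7.87, Tef 7.74, Per2 7.52, Bhlhe40 7.36 and Hlf 7.12. Intermediate heights were found at Ciart (6.18), Npas2 (5.64), Csnk1d (5.54), Per3 (4.99) and Cry1 (4.70). Nfil3 (3.65), Clock (3.05), Rora (2.72), Bhlhe41 (2.28) and the casein kinase gene Csnk1e (1.54) were lowest, and of the 22 only Csnk1e lay under the median of all protein-coding genes. Output genes of the clock in liver were open as well: 20 of 20 had a promoter peak, with a median of 5.51 (99.85th percentile), from Por (11.1) and Coq10b (8.66) down to Cyp2a5 (1.66). With a single time point, no rhythm of these heights could be measured.

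Hepatocyte genes had more open promoters than matched random lists, and no member lacked a peak. Genes of secreted plasma proteins had a median height of 5.65, where matched random lists had 0, led by Apoa2 (10.6), Ahsg (8.39) and Ttr (7.10) and closed by Serpina1a (2.90). Genes of liver transcription factors had a median of 6.55 against 2.22, from Nfia (10.0), Nr5a2 (8.61) and Nr0b2 (7.76) to Prox1 (2.37). Both lists exceeded all 10000 random lists. Coagulation and complement genes (19 of 19 with a peak, median 4.62) also exceeded all of them, with C3 (8.35), Proc (7.23) and Kng1 (5.84) at the top and C8b (2.37) at the bottom.

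Metabolic pathways of the liver were open together. Bile acid and cholesterol genes (18 of 18, median 5.49) were led by Cyp8b1 (8.70), which makes cholic acid, Abcb4 (8.36) and Hmgcs1 (8.00), with Cyp7b1 (2.27) lowest. Genes of fasting and gluconeogenesis (16 of 16, median 6.48) ranged from Angptl4 (11.9) and Slc25a47 (11.2) to Fgf21 (1.88), whose peak also lay within 1 kb of a TSS of Fut1. Urea cycle and amino acid genes (16 of 16, median 5.91) ranged from Uroc1 (10.2), Arg1 (7.84) and Asl (7.56) to Otc (1.69), and drug metabolism genes (18 of 18, median 5.21) from Ugt1a1 (20.04), Por (11.1) and Ces1d (7.93) to Cyp2a5 (1.66). These 4 lists exceeded all random lists. Lipogenic genes (14 of 14, median 6.13, 99.90th percentile) included Acly (8.15) and Thrsp (8.02), with Me1 (2.01) lowest, so that genes of fasting and of feeding were open in the same sample. The Ugt1a1 peak lay in the stretch of tall peaks on chromosome 1, and without that stretch and the isolated tall peaks the drug list kept a median of 4.96, above all random lists.

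Genes of both zones of the liver lobule were open. Periportal genes (14 of 14, median 5.54, above all random lists) were led by Gls2 (8.18), Arg1 (7.84) and Igf1 (7.12), with Aldh1b1 (1.66) lowest. Pericentral genes (14 of 14, median 4.69, 99.20th percentile) included Rnf43 (5.87) and Cyp2e1 (5.75), with the glutamate transporter gene Slc1a2 (0.477) lowest. The 2 lists were not tested against each other.

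Of the sex-biased liver genes, all 15 male-biased ones had a promoter peak and 13 of 18 female-biased ones did. The male-biased median was 2.76 (98.93rd percentile of matched lists), led by Nudt7 (8.13), C6 (6.74) and Cyp2d9 (6.07), with Moxd1 (0.233) lowest. The female-biased median was 0.317 (99.27th percentile, matched lists having a median of 0, but 49.7th among peaks at or above the median height), led by Cyp17a1 (10.9), Fmo2 (5.54) and Abcd2 (3.41), and Sult2a1 was among the 5 genes without a peak. The Cyp17a1 peak lay well inside that gene, with its midpoint 1032 bases from an annotated TSS, so its height need not describe the main promoter. Against random lists not matched on CpG content, neither stood apart, with the male-biased list at the 74.7th and the female-biased list at the 11.8th percentile.

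Glucocorticoid-responsive genes (14 of 14) had a median of 5.14 (98.46th percentile), led by Per1 (8.81), the phosphatase gene Dusp1 (7.13) and Pck1 (7.05), with the metallothionein gene Mt2 (0.729) lowest. Immediate early and stress genes (14 of 14) had a median of 5.14 as well, which at the 90.92nd percentile did not stand apart, although it did against unmatched lists (99.54th), with Jun (10.1), Atf3 (7.53) and Zfp36 (6.18) highest and Ier3 (1.17) lowest. Housekeeping genes, which most cells use, had peaks in 17 of 17 cases and a median of 6.09 (99.54th percentile), with Ywhaz (8.48), Rpl13a (7.57) and Rplp0 (7.32) highest and Hprt (1.94) lowest.

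Markers of Kupffer, endothelial and stellate cells had low but frequent peaks in the larger list. Among peaks at or above the median height only 3 of 15 Kupffer and 6 of 14 stellate genes kept one, no more than in matched lists (20% and 50%), while 10 of 15 endothelial genes did, against 40%. In the smaller run A list 12 of 15 Kupffer, 12 of 15 endothelial and 9 of 14 stellate genes had one, against 20%, 46.7% and 57.1%. Kupffer cell genes had a peak in 14 of 15 cases, where matched lists had 26.7%, with a median height of only 0.323 (99.80th percentile); Fcer1g (4.24), Cd68 (0.867) and Spi1 (0.481) were highest and Csf1r had none. Without the CpG match the Kupffer list lay at the 15.6th percentile, so its place depended on comparison with promoters as poor in CpG. Genes of sinusoidal endothelium (14 of 15, median 0.578, 86.94th percentile) were led by Stab2 (3.79), Tie1 (3.55) and Fcgr2b (1.72), with none at Lyve1. Stellate and mesenchymal genes (13 of 14, median 0.312, 26.68th percentile) were led by Pdgfra (2.89), Col1a1 (2.79) and Reln (0.837), with none at Acta2. Among cholangiocyte genes (7 of 10 against 80.0% in matched lists, median 0.864, 15.16th percentile), Sox9 (4.99) and Krt8 (3.77) were highest. Blood cell genes had peaks no more often than matched lists, in which 42.9% of genes had one for lymphocytes and 40% for neutrophil and erythroid genes. Peaks were found at 4 of 14 lymphocyte genes (share at the 7.50th percentile), led by Lck (2.53), Pax5 (2.11) and Ptprc (0.282) with none at Ncr1, at 3 of 10 neutrophil genes, namely Elane (5.04), S100a8 (0.353) and Csf3r (0.229) with none at Cxcr2, and at 4 of 10 erythroid genes, among them Alas2 (0.680) and Tal1 (0.571) with none at Hemgn. The Stab2, Lck and Pax5 peaks lay at annotated TSS inside these genes. The Fcer1g peak lay inside its gene, with its midpoint 1046 bases from a TSS and the plasma protein gene Apoa2 close by. Which cells opened it was not measured.

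Among genes of tissues that were not sampled, the germ cell and the gut and pancreas lists had peaks in a smaller share than matched lists in every setting. Germ cell genes had 1 peak in 10, at Dazl (2.08), where matched lists had 80.0%, and the list median of 0 lay at the 0.33rd percentile. Among peaks at or above the median height this median was no longer low. Gut and pancreas genes had 2 in 12 against 58.3% in matched lists (share at the 0.01st percentile, and at most at the 0.43rd in the alternatives), at Ins2 (4.31) and Nkx6-1 (0.537), and kidney genes 3 in 10 against 60% (share at the 4.21st percentile), at Slc12a3 (7.53), Nphs1 (4.78) and Umod (0.567). The Slc12a3 and Nphs1 peaks, and that of Rbfox3 named below, lay at annotated TSS well inside these genes. Muscle genes had 5 in 13 against 53.8% (share at the 18.6th percentile), at Ckm (1.73), Ttn (1.70), Actn2 (1.32), Myl2 (0.492) and Mb (0.116). Neural genes had 11 in 14, the same share as in matched lists, with Gfap (2.07), Syn1 (1.13), Rbfox3 (1.06), Snap25 (0.931) and Olig2 (0.792) highest, but their median of 0.419 lay at the 2.54th percentile, against 2.43 in matched lists, and was low within 500 bases (0.90th), among peaks at or above the median height (1.01st) and in the smaller run A list (1.81st). It was not low in the main setting or against unmatched lists.

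**Figure D2:**
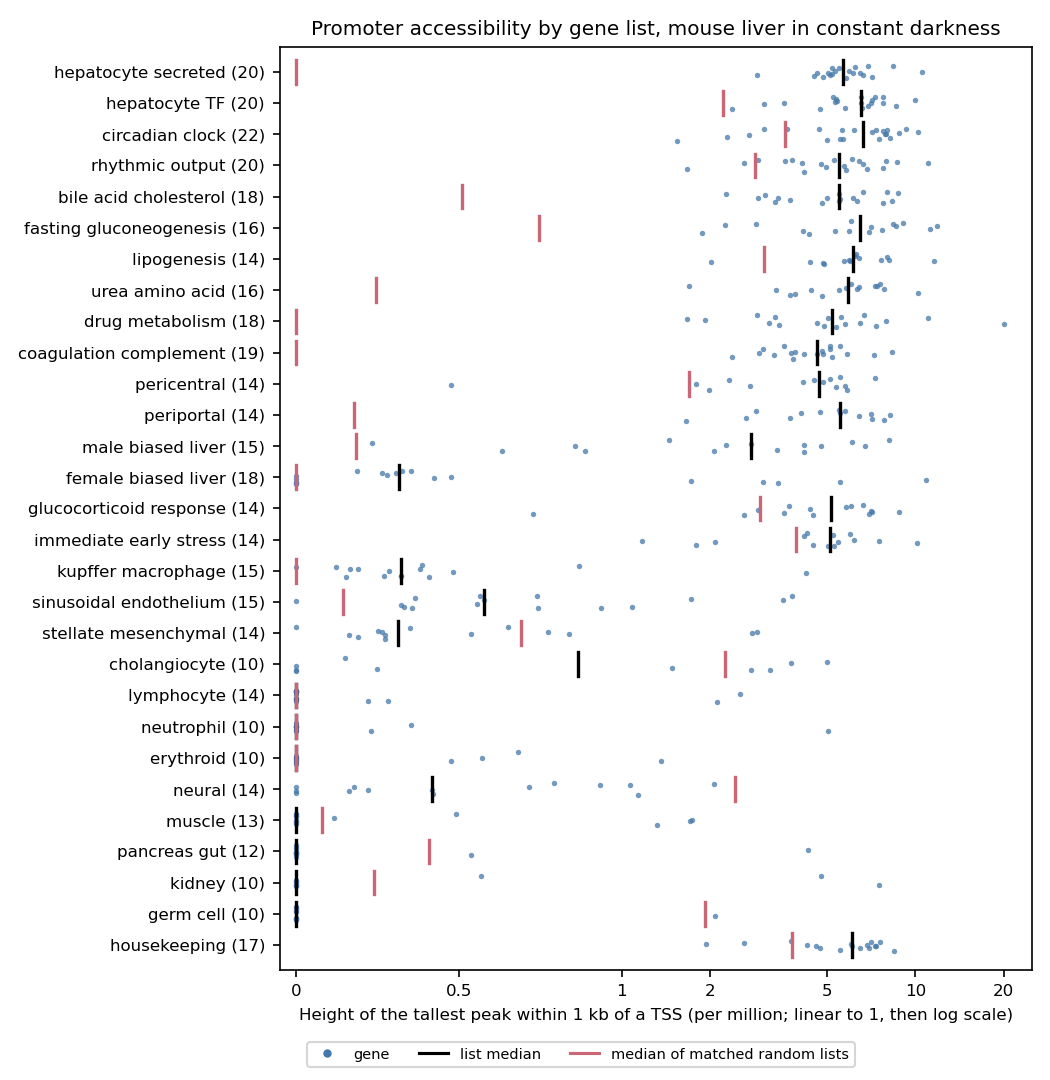
Height of the tallest peak within 1 kb of a TSS (horizontal axis, depth-scaled units, linear to 1 and logarithmic above) for each gene (points) of the 29 lists, with the number of genes used beside each name; black lines are list medians and red lines the medians of matched random lists. The median is 6.65 for the clock genes and 5.65 for secreted plasma proteins, and the medians of the muscle, gut and pancreas, kidney and germ cell lists are 0.

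Peaks also crowded around the same genes. Within the gene or 10 kb of it, the median number of peaks was 30 for secreted plasma proteins, where random lists matched on gene length had 5, and 30 for liver transcription factors, where they had 8.5. Lipogenic genes had 35.5, urea cycle and amino acid genes 34, periportal genes 34, drug metabolism genes 33 and bile acid and cholesterol genes 29. Clock genes had a median of 20 against 8.5, with 160 at the long gene Rora, 49 at Hlf and 42 at Per2, and all of these lists exceeded all 10000 random lists. Male-biased genes had 15 (98.77th percentile, and 97.4th within the gene alone, which was not high) and female-biased genes 8 (35.98th percentile), against 9 and 8.5. Kupffer cell genes had 6, as matched lists did, and neural genes had 5 against 9.5 (1.75th percentile). The low place of the neural genes was lost within 50 kb (15.6th percentile), in the gene alone (6.35th), with unmatched lists (15.8th) and in the smaller run A list (7.92nd).

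Footprints held the recognition sequences of liver and general factors. Of 34 motifs, 14 were denser in footprints than in the rest of the peaks by a ratio above those of all their shuffled versions. CTCF sites were 54.9 times as dense (95% counting interval 50.9 to 59.3), with 5887 sites in footprints and 765 elsewhere, and NRF1 sites 60.2 times (43.0 to 86.5), or 14.2 times (8.04 to 26.0) outside promoters. Among liver factors, HNF1 sites were 33.1 times as dense (15.1 to 82.6, on 35 and 8 sites), C/EBP sites 14.7 (12.6 to 17.1), HNF4 sites 12.7 (11.2 to 14.5), NFI sites 11.01 (8.72 to 13.9), NR5A2 sites 3.36 (3.09 to 3.65, not above all shuffles without a flank) and ONECUT sites 2.09 (2.00 to 2.19). CRE, YY1, ETS and NF-Y sites had ratios of 12.2, 8.37, 5.30 and 2.47, and TEAD sites 1.18 (1.07 to 1.31), which was lost with either other flank. Outside promoters the ratios of CRE, YY1 and ETS sites were 6.93, 5.81 and 1.81, and those of YY1 and ETS no longer exceeded all shuffles.

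Of the clock elements, the D-box, which DBP, TEF, HLF and NFIL3 bind, was 2.41 times as dense in footprints (2.26 to 2.566) and exceeded all its shuffles. The E-box of CLOCK and BMAL1 was 1.99 times as dense (1.90 to 2.07) and the RORE, which REV-ERB and ROR proteins bind, 1.76 times (1.54 to 2.00), and both stayed under the highest shuffle, at 3.54 and 1.88. Without a flank the RORE ratio was 0.803 (0.557 to 1.12). FOXA sites had a ratio of 0.742 (0.661 to 0.831), GATA sites 0.328, POU sites 0.739, MEF2 sites 0.717 and STAT5 sites 0.876, all within the range of their shuffles. The median shuffle was below 1 for each, at 0.444, 0.471, 0.682, 0.492 and 0.697 in that order. For these motifs a ratio below 1 is thus no sign of depletion beyond that of shuffled sites. Of them, only GATA lay under its median shuffle. SREBP sites (0.772, interval 0.663 to 0.895) and MYOD sites (0.846, 0.770 to 0.928) were also less dense in footprints. Both lay under their median shuffles, at 0.980 and 1.25, but within the range of their shuffles. With footprints widened by 10 bases FOXA (1.03, interval 0.948 to 1.12), MEF2 (1.05) and STAT5 (0.997) sites no longer differed from 1. Sites of AP-1 (1.01, interval 0.962 to 1.06) and of the glucocorticoid receptor (0.818, 0.581 to 1.12) did not differ from 1, although with footprints widened by 10 bases the latter had a ratio of 1.24 (1.003 to 1.51). Outside promoters AP-1 sites had a ratio of 1.09 (1.03 to 1.15), within the range of their shuffles. The motifs for PPAR with RXR (8.89, 6.15 to 12.9), SP and KLF factors (13.2), RFX (14.7), REST (14.7) and P53 (1 site in each part) had too few usable shuffles to be placed.

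**Figure D3:**
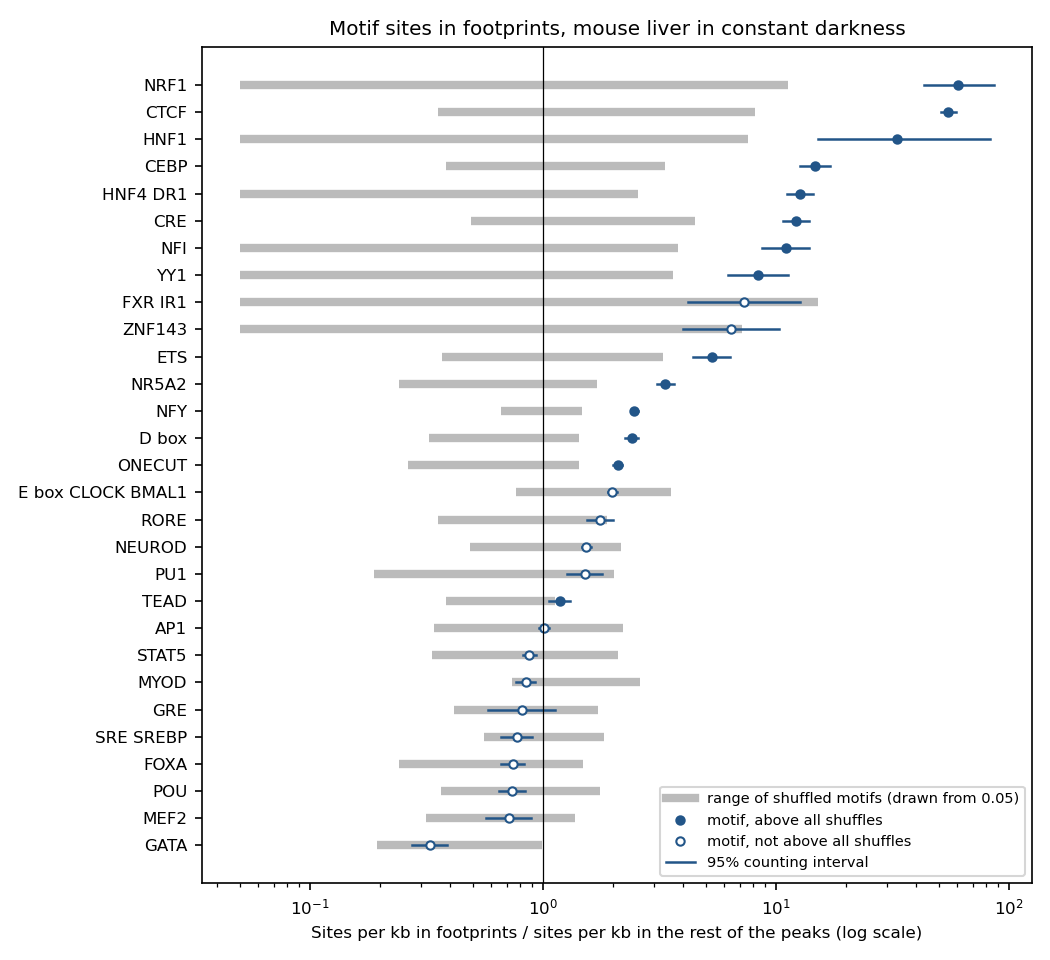
Ratio of motif sites per kb in footprints to those in the rest of the peaks (horizontal axis, log scale) for the 29 motifs with at least 10 usable shuffles; points are motifs, thin lines 95% counting intervals and grey bars the range over up to 20 shuffled versions. Filled points, from TEAD at 1.18 to NRF1 at 60.2, exceed all their shuffles.

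Away from promoters, the centres of peaks were rich in the same liver motifs and also in FOXA. In 177889 peaks over 1 kb from any TSS, 18 of the 34 motifs were more frequent within 100 bases of the centre than in equal windows beyond the peak by more than in all shuffles. HNF4 sites were found in 0.535% of the centres (95% Wilson interval 0.502 to 0.570) and 0.0585% of the flanks, C/EBP sites in 0.320% and 0.0242%, and CTCF sites in 3.38% and 0.0641%. FOXA sites were found in 1.63% of the centres (1.57 to 1.69) and 0.779% of the flanks, a ratio of 2.09 that exceeded all shuffles. ONECUT sites (4.56% and 2.52%), NR5A2 sites (1.097% and 0.512%), RORE sites (0.687% and 0.349%) and D-box sites (2.09% and 1.65%) also exceeded their shuffles. E-box sites (3.44% and 2.35%, ratio 1.46) and glucocorticoid receptor sites (0.234% and 0.129%, ratio 1.82) did not. In the peaks at or above the median height, glucocorticoid receptor sites exceeded their shuffles, AP-1, PU.1, ETS and NR5A2 sites no longer did, and RFX had too few usable shuffles to be placed.

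The 2 processing runs, which share the same libraries and therefore show processing differences only, placed most open sites alike. Of the larger run A list, 94.0% of peaks (interval 93.9 to 94.1) overlapped a run B peak by at least 1 base, against 3.82% after random placement, and 91.2% of run B peaks overlapped run A. Across the 235100 shared run A peaks, the heights of both runs had a Spearman correlation of 0.999 and a Pearson correlation of 0.995, over peaks that are not independent replicates. Peaks shared with run B had a median height of 0.499 and those not shared 0.176. At an FDR of 0.05, run A marked 107 Mb and run B 110 Mb, and 89.5% of the bases marked by either were marked by both. Overlap of at least 50% of both peaks held for 72.4%. Run B peaks were at most 150 bases wide, while run A peaks had a median of 200 and reached 3260. Wide run A peaks could therefore not meet this criterion wherever the run B peak lay.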

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

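Of 29 gene lists, 17 were high by promoter height, and 15 to 17 with other windows, other peak lists, the peaks at or above the median height, unmatched random lists or, chosen after seeing the data, without the doubtful tall peaks. The female-biased and Kupffer cell lists dropped out in the peaks at or above the median height, and these and the male-biased list with unmatched lists, where the Kupffer cell list fell from the 99.80th to the 15.6th percentile and the female-biased list from the 99.27th to the 11.8th. The immediate early list became high there (99.54th), so that 14 of its 15 high lists were among the 17. By number of peaks 16 lists were high, and 14 to 16 in the alternatives, the pericentral list being lost within 50 kb, the male-biased list within the gene alone, and the immediate early and housekeeping lists with unmatched lists. By height 1 list, the germ cell genes, was low, and 1 to 2 in the alternatives with matched lists. Among peaks at or above the median height the 1 low list was the neural one, and the germ cell genes were no longer low. A list median of 0 cannot fall further, and by share with a peak the germ cell and the gut and pancreas lists stayed low in every setting. With unmatched lists 6 were low, adding lymphocyte, neutrophil, erythroid, gut and pancreas and kidney genes. By number of peaks 1 was low, and 0 to 2 in the alternatives. Motifs above all shuffles numbered 14 in footprints, 12 to 14 in the alternatives including the footprints at or above the median length, and 18 in distal peaks, 14 to 18 in the alternatives. In footprints TEAD was lost under each other flank and in the longer footprints, NR5A2 without a flank, ETS and YY1 outside promoters and YY1 in the longer footprints, while ZNF143 was gained in all but the setting outside promoters. The ratios themselves moved by more than 1.5 times with the flank: without one CTCF went from 54.9 to 178, HNF4 from 12.7 to 37.7 and RORE from 1.76 to 0.803. No list passed from the high to the low tail. Shares without a test moved beyond their counting intervals. Peaks shared between runs went from 94.0% to 72.4% for an overlap of 50% of both and to 99.3% in peaks at or above the median height. The first of these settings shuts out wide run A peaks, as run B peaks were at most 150 bases wide. The promoter share went from 19.7% to 13.1% within 500 bases, 31.4% within 2500, 16.5% with protein-coding genes, 26.4% in peaks at or above the median height, 22.6% in the smaller run A list and 19.4% in run B, the last 2 chosen after seeing the data. The correlation of heights was 0.999 on log2 values and 0.998 in peaks at or above the median height. Bases marked by both runs were 89.2% at FDR 0.01 and 88.6% at 0.001. A stricter part of the footprints was not run, as all carry 1 value. No paired analysis was possible because the files pool both libraries of the only group, and for the same reason no library could be left out. Heights reach down to 6 cuts in the larger list, so depth limits what can be said of genes without a peak.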

Other observations

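Chosen only after the result was seen were the tests of the stretch near Ugt1a1 against other dense stretches, of the difference between runs at isolated tall peaks, and of the Y-linked promoter peaks against copies. E-boxes in the promoter peaks of clock genes lay in footprints more often than elsewhere. In 117 promoter peaks of the 22 clock genes, 23 CACGTG sites were found, of which 18 (78.3%, 95% Wilson interval 58.1 to 90.3) lay within a footprint or 5 bases of it, against 1007 of 3317 (30.4%, 28.8 to 31.9) at other protein-coding genes. Per1 had 3 such sites, all in footprints, on chromosome 11 at 69094883, 69095067 and 69098783, the second in the sequence CCCCCGCCCTCACGTGGCTCTATCAC. Ciart had 3 of 3 in footprints within 1 peak on chromosome 3, Dbp 2 of 2, and Cry1, Hlf, Nfil3, Npas2 and Bhlhe41 1 of 1, while Tef had 2 of 4, Bhlhe40 1 of 2 and Nr1d2 1 of 3. D-boxes were found in 8.55% of the clock promoter peaks (4.71 to 15.02) and in 1.43% of the others (1.32 to 1.55), and 4 of 11 lay in footprints, at Nr1d2, Per2, Per3 and Rora. The 2 RORE sites, at Dbp and Npas2, lay outside footprints. The E-box sites of clock genes lay in taller peaks, at a median of 5.66 against 1.66, and tall peaks may simply yield more footprints. Among 10000 draws of E-box sites from other promoter peaks of like height, the median was 12 in footprints (95% of draws from 8 to 17), and the observed 18 stood at the 99.53rd percentile, which is in line with occupancy beyond what height gives. For D-boxes the observed 4 equalled the median of such draws. Sites within 1 peak are not independent, and which protein sat on them was not measured.

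The tallest peaks on chromosome 1 formed a stretch of 76.6 kb from 88211801 to 88288380 over Ugt1a1, Mroh2a, Hjurp and the start of Trpm8, with 9 of the 30 tallest peaks of the genome. Extra copies of this DNA in these mice against the reference may raise every peak in it. The lower quartile of its 63 heights, 0.672, stood at the 99.66th percentile of stretches of as many neighbouring peaks. Outside peaks, 27.8% of its bases reached FDR 0.05 against 6.56% within 100 kb on each side. The stretch was picked for its tall peaks, and its median height stood at the 99.61st percentile too. The lower quartile therefore cannot tell extra copies from a dense cluster. A dense cluster of strong single-copy sites remains open, because the lowest peak of the stretch, 0.376, equalled the highest found among 979 other stretches with as high a median and stood at the 99.69th percentile of them. Runs of neighbouring peaks all at least that high were found elsewhere too, the longest of 79 peaks on chromosome 4, against 68 around this stretch. Reads from near-identical sequence elsewhere would have given most of its tall peaks a second match. One was found for 11.1% of them (1 of 9, interval 1.99 to 43.5), against 7.50% of random tall peaks. These values argue against reads from such sequence on the assembled chromosomes as the source of most of the 9 peaks searched. Unplaced sequence was not searched. The rule set beforehand to drop this explanation, a share at or below that of random peaks, was not met, so by that rule it stayed undecided. The genomes of these animals were not analysed here.

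The other tall peaks away from coding TSS, 14 of the 30 tallest, may collect reads from copies of their sequence. A second match was found for 71.4% of them (10 of 14, interval 45.4 to 88.3) and for 14.6% of random peaks over 1 kb from a coding TSS (12.5 to 16.9), and none matched mitochondrial DNA. The height differed over 1.5 times between the runs in 28.6% of them (4 of 14) and in 0.201% of the other peaks of the strongest 1%, which leaves open how far differences in the reads kept play a part. Peaks at Kpna1 and Lars2 had 10 and 9 other matches. The peaks nearest to Ifna13, Slc12a3, Irf2bp2 and Ide had none, with heights of 20.4, 14.04, 13.8 and 13.4. For the peak nearest to Ifna13 the run B height was 3.08 times that in run A after scaling by the typical ratio of the runs. No biological explanation was tested.

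Chromosome Y carried 132 peaks although the sex of the animals was not collected. The promoters of 4 Y-linked genes, Ddx3y, Uty, Kdm5d and Eif2s3y, all held a peak (4 of 4), as DNA of male animals in the sample would give. Of the tallest peaks at these 4 promoters, 0 had a match on another chromosome, which argues against reads from near-identical copies there as their source. A lower peak beside that of Ddx3y (1285781 to 1286380, 0.841) did have such a match. For the rest of the chromosome copies could contribute, as 51.5% of its peaks (43.1 to 59.9) had a match on another chromosome. How many animals were pooled, and whether females were among them, was not given in the labels.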
